A study of Mus musculus with 12 samples.

How the data were processed

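Expression was measured on 12 single-colour Illumina bead arrays, 6 of DNAM-1 positive and 6 of DNAM-1 negative NK cells sorted from mouse spleen, with 3 arrays of each group on each of 2 slides. Groups and sample numbers came from the sample titles. RNA was extracted on silica columns and treated with DNase, and biotinylated cRNA was prepared from it, per the labels' protocols. The deposited raw table holds 1 intensity per probe and array on a linear scale, marked as raw in the file header and summarised with GenomeStudio, per the submitters' processing notes; its version and any background step are not given in the sources used here. The same deposited table holds a detection p-value for each probe and array, per the file headers, and how it was computed is not given. The deposited series values are on a log2 scale: recomputed from the raw intensities, they equalled the quantile-normalized log2 signal minus each probe's median over the 12 arrays to within 0.00168, with column medians between -0.00108 and 0.00268. Their scale, centring and direction were settled by this recomputation, and they were used as an alternative.

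Background was corrected with the normexp model of limma's neqc, using the detection p-values and an offset of 16, followed by quantile normalization and log2. Of the 45281 probes, 34885 had 1 gene symbol in the platform annotation, 18 had several and 10378 had none there. Of those with 1 symbol, 34807 matched the reference gene table by Entrez identifier, and 0 symbols changed on update. Probes were kept if their detection p was under 0.05 on at least 6 of the 12 arrays, which left 18201. A gene was represented by its probe with the highest mean, and a probe with no or several symbols stood for itself, which gave 12213 features. Of the genes with several kept probes, 2 had 1 probe called higher and another lower, Jak1 and Kif1c. No genomic coordinates are given, because no genome build is named in the sources used here.

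Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the group as the only term, two-sided, and with Benjamini-Hochberg adjustment over all features at 0.05. Lists of genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 30 of 31 lists with at least 4 measured genes; fry, which tests whether a list's genes move one way on balance, was run beside it. Of 10 shifted lists, 6 also passed with an estimated correlation: T cell, ILC1, immature NK, mature NK, Ly49 and proliferation. By fry 13 lists passed, 9 of the 10 among them. The interaction of group and slide was tested in a separate fit. The design, lists, gene naming rule and alternative settings other than the 1 named last below were fixed before the data were examined. By that rule the text names Cd226, the genes of the other sorting markers and up to 4 members with the smallest p of each list. It also names the 12 genes with the largest change in each direction among called genes with 1 symbol whose groups did not overlap. Some list members that the rule picks but that were not called are left out. Other genes are marked as named after their values were seen.

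The series design states 6 groups of mice. The labels do not say that a sample number marks one of them, so the p-values measure the spread between these samples, part of which may be technical. No 2 arrays were identical (correlation over probes between 0.964 and 0.993), and all 12 were used. The number of arrays limits the precision. The fit was tested on simulated arrays with the measured means and spreads of the 12213 features. With 50 genes changed at each size in the comparison of DNAM-1 positive and DNAM-1 negative samples, it recovered 32% of genes with a log2 change of 0.5, 90% at 1, 100% at 2 and 100% at 3, and 6.52% of its calls were false. Of the lists, 0 were called apart from the 1 that was shifted. The simulated features varied independently of one another. The list result therefore does not cover lists with correlated members, such as the B cell list (estimated correlation 0.57). Alternatives covered the background correction, the normalization, the deposited values, the detection filter, the choice of probe, array weights, an intensity trend, the slide and the sample number as blocks, each slide alone and each array left out in turn. Leaving out samples 5 and 6 of both groups was added after seeing the data.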

Results

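Natural killer (NK) cells were sorted from the spleens of wild-type C57BL/6 mice as cells positive for NK1.1 and NKp46 and negative for CD3, and were split by surface DNAM-1, an adhesion and activating receptor encoded by Cd226. Total RNA of 6 DNAM-1 positive and 6 DNAM-1 negative samples was hybridised to 12 Illumina expression arrays, which lay on 2 slides with 3 arrays of each group per slide. Between 39.8% and 42.3% of the 45281 probes were above background on each array. The number of arrays limits the precision of every value below. The design implied 1 comparison, the transcripts that differ between DNAM-1 positive and DNAM-1 negative NK cells. Differences are given as log2 intensity in DNAM-1 positive minus DNAM-1 negative cells, with the standard error from the limma fit (n = 6 arrays per group).

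The transcript of the sorting marker checked the labels. Cd226 differed by 4.67 ± 0.14 (adjusted p = 8.6e-11), with a level of 9.35 ± 0.20 (SD) in DNAM-1 positive and 4.68 ± 0.31 (SD) in DNAM-1 negative samples, a 25.5-fold ratio in which 2 of the 6 DNAM-1 negative arrays were above background. Of the other probes of the gene 1 was at least 16.1-fold higher and 1 differed by 1.43, and the remaining probe was not above background on any array. Of the genes behind the other sorting markers, Ncr1 (NKp46) differed by -0.12 ± 0.17 (adjusted p = 0.749) and Klrb1c (NK1.1) by 0.05 ± 0.10 (adjusted p = 0.852). Cd3e, which encodes a chain of the CD3 complex used to exclude T cells, was higher in DNAM-1 positive cells on every array, at 10.33 ± 0.12 (SD) against 4.62 ± 0.08 (SD).

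DNAM-1 positive samples held more RNA for the CD3 chains of Cd3d, Cd3e and Cd3g, the IL-7 receptor, ILC1-associated membrane proteins, IL-2 and the cell division machinery. They held less RNA for several Ly49 receptors, the steroid hydroxylase Cyp17a1 and the adhesion molecule Mcam. Each array measured a whole sorted sample, so the differences given here do not show which cells in it held the RNA. Of 12213 features tested (9292 genes with a symbol and 2921 probes without a single symbol), 827 changed at an adjusted p under 0.05, of which 510 were higher and 317 lower in DNAM-1 positive cells. Among these, 149 differed at least 2-fold, 119 upwards and 30 downwards, and 32 did so without background correction and 38 with the deposited values, which lack it. The values of the 2 groups did not overlap for 659 of the 12213 features, 582 of them among the 827, where chance gives this for 0.216% of features. With the slide as a block 872 features changed. Slide 1 alone gave 328 (245 higher, 83 lower) and slide 2 alone 174 (129 higher, 45 lower), each with 3 arrays per group and normalized by itself. Scaling arrays to a common median instead of quantile normalization turned the split, with 285 higher and 373 lower, and leaving out DNAM-1 positive sample 2 reduced the lower features to 202.

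**Figure D1:**
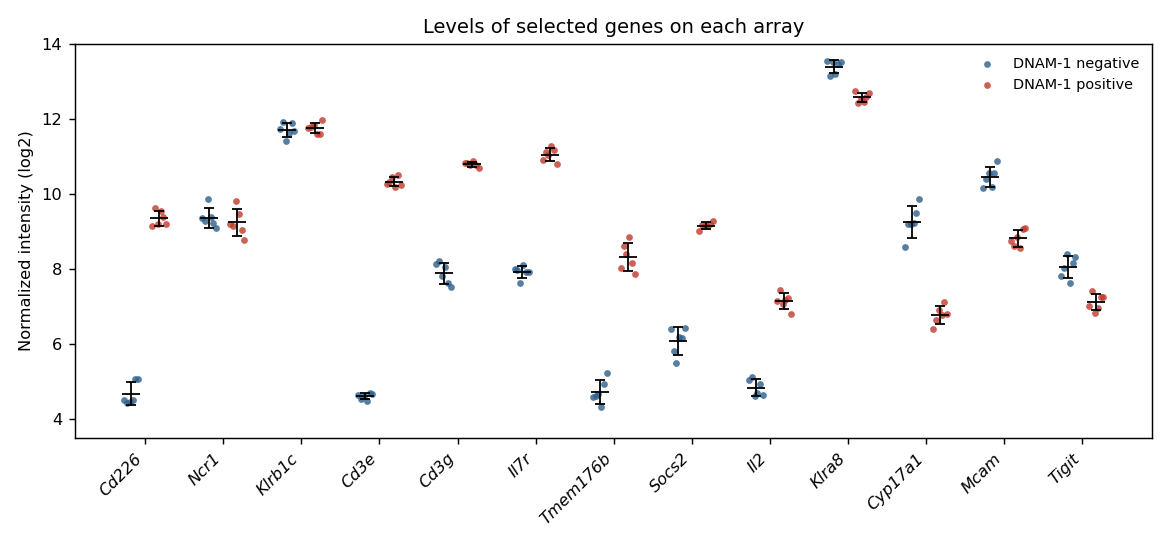
Normalized intensity (log2, vertical axis) of selected genes on each of the 12 arrays; points are arrays, horizontal bars are group means and error bars are SD (n = 6 per group). Cd226 and Cd3e separate the groups widely, Ncr1 and Klrb1c overlap, and Klra8, Cyp17a1, Mcam and Tigit are lower in DNAM-1 positive samples.

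Most measured markers of T cells were higher in DNAM-1 positive samples. The list had 13 members on the array, of which the detection filter left out Cd4, Cd5, Cd8a and Themis. No probe of these genes was above background on any DNAM-1 positive array. Of 9 measured T cell markers 8 rose and none fell (8 adjusted over the list alone), with a median difference of 1.82 that was 1.86 on slide 1 and 1.78 on slide 2 (camera adjusted p = 6.6e-23, and adjusted p = 2.8e-05 with an estimated correlation). Where a probe was not above background on any array of the lower group, its ratio is given as a lower bound, computed against the lowest signal among detected probes of each array or the probe's own signal if higher. With the 3 members whose representative probe has only such a bound set at it, the median was 1.44. The medians for each slide were not bounded in this way. Cd3e was at least 44.9-fold higher (difference 5.71 ± 0.07, adjusted p = 2.8e-15), although its second probe was above background on 3 DNAM-1 negative arrays. Cd3g rose by 2.91 ± 0.11 and Cd3d by 2.68 ± 0.10, and both were also above background on all 6 DNAM-1 negative arrays. Cd247, the gene of the CD3 zeta chain, named after its value was seen, differed by 0.06 ± 0.24 (adjusted p = 0.923). The representative probe of Cd6, a co-receptor of T cells, was at least 2.64-fold higher (adjusted p = 4.5e-09), and its other probes at least 2.52-fold and 1.96-fold, although a Cd6 probe was above background on 1 DNAM-1 negative array. Trgv4, a T cell receptor gamma chain variable segment, was above background on all DNAM-1 positive arrays and no DNAM-1 negative array and was at least 16.1-fold higher (adjusted p = 2.8e-13).

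Markers of type 1 innate lymphoid cells (ILC1), a population related to NK cells, were higher in DNAM-1 positive samples. Of 9 measured members 8 rose and none fell (9 rose adjusted over the list alone), with a median of 1.55, 1.69 on slide 1 and 1.56 on slide 2 (camera adjusted p = 3.3e-22, and adjusted p = 0.00183 with an estimated correlation). Tmem176b rose by 3.60 ± 0.18, with 2 of 6 DNAM-1 negative arrays above background, and its neighbour in name Tmem176a was at least 3.26-fold higher (adjusted p = 2.0e-07). Ckb, the brain-type creatine kinase, rose by 3.55 ± 0.22, the transcription factor gene Rora by 1.55 ± 0.15, and Tnfsf10, which encodes the death ligand TRAIL, by 1.49 ± 0.12 (0.63 on its other probe). Cxcr6 was at least 2.17-fold and the integrin gene Itga1 at least 1.72-fold higher, neither being above background on any DNAM-1 negative array.

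Immature NK cell markers were higher and mature NK cell markers lower. Of 12 immature markers 7 rose and none fell (10 rose adjusted over the list alone; median 0.68, 0.64 on slide 1 and 0.68 on slide 2; camera adjusted p = 7.8e-13, and adjusted p = 0.00479 with an estimated correlation). Il7r, the IL-7 receptor chain that is also in the ILC1 list, rose by 3.13 ± 0.10 (adjusted p = 1.2e-10; 1.68 and 2.44 on 2 other probes and at least 2.08-fold on another), the oxysterol receptor gene Gpr183 by 2.24 ± 0.14, Thy1 by 1.26 ± 0.07 and the chemokine receptor gene Cxcr3 by 0.91 ± 0.09. Of 10 mature markers 2 fell and none rose (4 fell adjusted over the list alone; median -0.31, -0.34 on each slide; camera adjusted p = 8.8e-04, and adjusted p = 0.0269 with an estimated correlation). These were the mast cell protease gene Cma1, at -0.72 ± 0.11, and S1pr5, a sphingosine phosphate receptor of lymphocyte egress, at -0.45 ± 0.08, with an uncalled second probe at -0.33 (adjusted p = 0.106). Tbx21, which encodes the transcription factor T-bet, differed by -0.36 ± 0.12 (adjusted p = 0.108) and Klrg1 by 0.25 ± 0.12 (adjusted p = 0.268), neither past the threshold.

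Ly49 receptors, the MHC class I receptors of mouse NK cells, were lower in DNAM-1 positive cells. Of 10 measured Klra genes 5 fell and none rose (5 fell adjusted over the list alone; median -0.26, -0.34 on slide 1 and -0.27 on slide 2; camera adjusted p = 8.5e-07, and adjusted p = 0.00262 with an estimated correlation). The probe annotated to Klra22 was 2.83-fold lower (adjusted p = 6.8e-08). On the log2 scale the representative probes annotated to Klra8, Klra16 and Klra4 fell by 0.82 ± 0.09, 0.57 ± 0.10 and 0.55 ± 0.07. Other probes annotated to Klra16 differed by -0.64 and -0.94, and to Klra4 by -1.04 and -1.42. Another Klra4 probe was at least 1.28-fold lower, and the other Klra22 probe differed by -1.11. Klra7, named after its value was seen, fell by 0.34 ± 0.07. These genes are related copies whose probes may hybridise to one another's transcripts, so the value of any single member is uncertain. Probe sequences were not used to check this. The members counted as called need not be separate genes for the same reason. In the related CD94-NKG2 and NKR-P1 list 2 of 10 members rose and 1 fell (the same counts adjusted over the list alone; camera adjusted p = 0.72), and the list's median of -0.05 and mean of 0.22 differed in sign. Klrb1b, an inhibitory receptor gene, rose by 2.16 ± 0.19, Klri1 rose by 0.57 ± 0.08 and Klri2 fell by 0.41 ± 0.09, a call that ended without samples 5 and 6 of both groups (adjusted p = 0.0672).

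Genes of cell division were higher in DNAM-1 positive cells. Of 29 measured proliferation genes 17 rose and none fell (20 rose adjusted over the list alone), with a median of 0.75, 0.77 on slide 1 and 0.74 on slide 2 (camera adjusted p = 3.1e-18, and adjusted p = 0.0398 with an estimated correlation). The mitotic spindle genes Nusap1 and Kif22 rose by 1.61 ± 0.15 and 1.28 ± 0.09, and the division genes Cdca8 and Cdca3 by 1.33 ± 0.14 and 1.23 ± 0.14. DNAM-1 positive sample 6 had a lower mean for this list, -0.03, than the other DNAM-1 positive samples, which lay between 0.35 and 0.50 relative to the mean of all 12 arrays. Ribosome biogenesis and MYC target genes did not shift, with 0 of 24 members called by limma (0 adjusted over the list alone; median 0.06; camera adjusted p = 0.221).

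**Figure D2:**
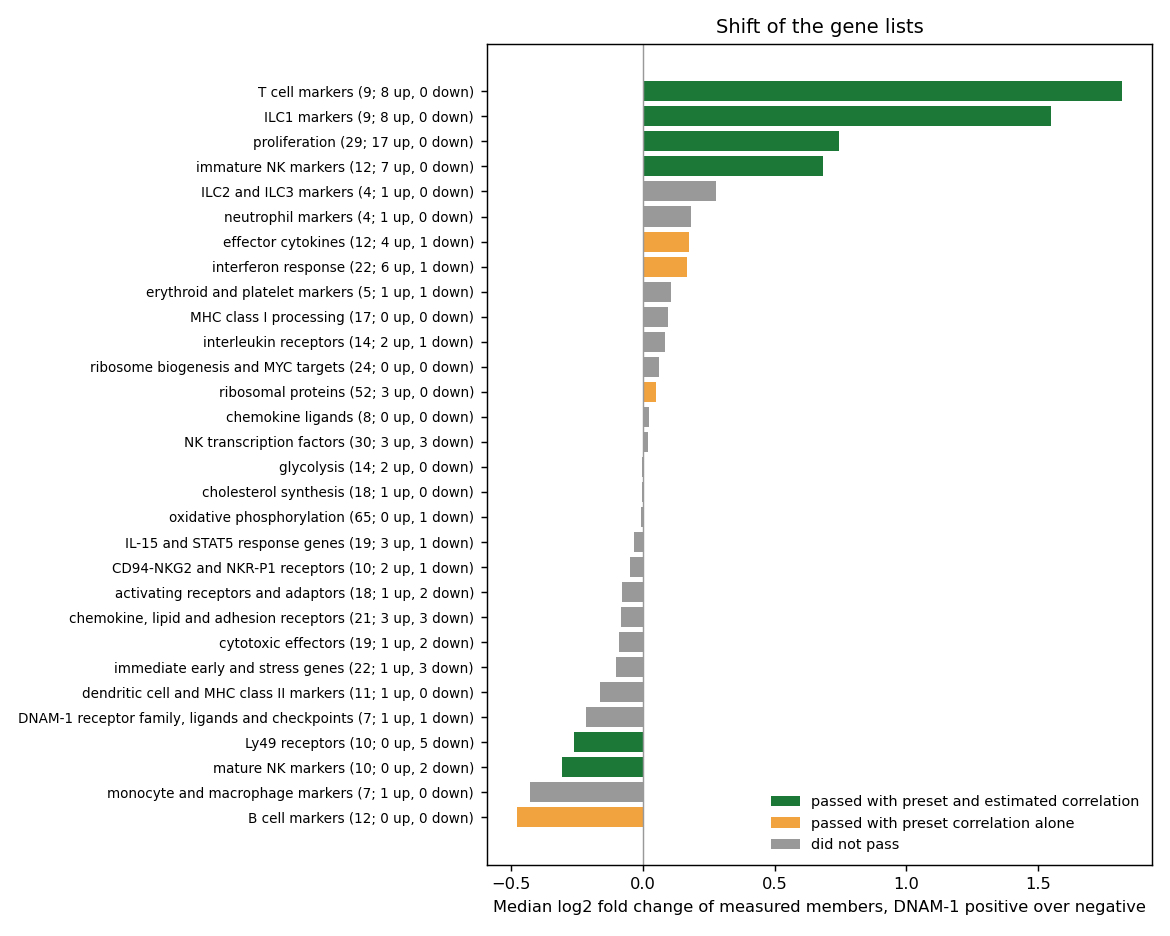
Median log2 difference of the measured members of each gene list, DNAM-1 positive minus DNAM-1 negative (horizontal axis, bars from 0); labels give the number of members measured and how many were called higher and lower. Green lists passed camera with a preset and with an estimated correlation, orange lists with the preset correlation alone, and grey lists passed neither; T cell markers have a fitted median of 1.82, or 1.44 with members at their bounds, ILC1 markers 1.55 either way, and B cell markers -0.48.

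Lymphocyte cytokine genes shifted upwards as a list with the preset correlation. Of 12 effector cytokines 4 were called higher and 1 lower (the same counts adjusted over the list alone), with a median of 0.18, 0.24 on slide 1 and 0.12 on slide 2 (camera adjusted p = 0.0175, and adjusted p = 0.161 with an estimated correlation). Il2, the gene of a T cell growth factor, rose by 2.30 ± 0.12, with 3 of 6 DNAM-1 negative arrays above background. The lymphotoxin genes Ltb and Lta rose by 0.98 ± 0.16 and 0.90 ± 0.16, and Lta was above background on 5 of 6 DNAM-1 negative arrays and not called on its other probe (0.44, adjusted p = 0.0623). Tnf, named after its value was seen, rose by 0.58 ± 0.16 (adjusted p = 0.0486). The representative probe of Tnfsf14 differed by -0.27 ± 0.08 (adjusted p = 0.0474), a call that ended with the slide as a block (adjusted p = 0.0532) and when any of 11 arrays was left out (adjusted p up to 0.111). The mean of the Tnfsf14 probes differed by -0.09 (adjusted p = 0.823), and its other probes by 0.23 (adjusted p = 0.82) and -0.22 (adjusted p = 0.37), so no direction is given for this gene. The interferon gamma gene Ifng, also named after its value was seen, differed by 0.02 ± 0.15 (adjusted p = 0.953). No chemokine ligand of 8 was called by limma (2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.995): Ccl3 differed by -0.41 ± 0.14, Ccl4 by -0.25 ± 0.07 and Xcl1 by 0.34 ± 0.12. The other probe of Ccl4 was called (-0.45, adjusted p = 0.00702), as was the mean of its probes (-0.35, adjusted p = 0.00931), and Ccl9 (0.90 ± 0.36) was called with the slide as a block (adjusted p = 0.0489).

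Genes induced by cytokine signalling through STAT5 included some of the large increases. Of 19 IL-15 and STAT5 response genes 3 rose and 1 fell (3 rose and 2 fell adjusted over the list alone), and the list did not shift by camera (median -0.03, mean 0.21, opposite in sign; camera adjusted p = 0.458), though fry passed (adjusted p = 3.2e-04). Socs2, Cish and Socs3, which encode inhibitors of cytokine signalling, rose by 3.07 ± 0.14, 1.22 ± 0.13 and 0.43 ± 0.07, and median scaling ended the call of Socs3 (adjusted p = 0.0736). The highest probe of Jak1 differed by -0.44 ± 0.11 (adjusted p = 0.0323), but its other probes differed by 0.48 (adjusted p = 0.00369) and 0.09, so no direction is given for this gene. Among 14 interleukin receptors Il7r and Il27ra (0.41 ± 0.09) rose and Il10ra fell by 0.55 ± 0.10 (the same counts adjusted over the list alone; median 0.08; camera adjusted p = 0.273, fry adjusted p = 4.2e-05). The Il27ra call ended with median scaling (adjusted p = 0.161) and without samples 5 and 6 of both groups (adjusted p = 0.0543), and its other probe was not called (0.16, adjusted p = 0.368).

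Interferon-induced genes were higher as a list with the preset correlation. Of 22 measured members 6 rose and 1 fell (8 rose and 1 fell adjusted over the list alone), with a median of 0.17, 0.10 on slide 1 and 0.19 on slide 2 (camera adjusted p = 0.0039, and adjusted p = 0.0954 with an estimated correlation). The antiviral genes Rsad2 and Ifit3 each rose by 0.80, with standard errors of 0.09 and 0.11, and Isg15 rose by 0.55 ± 0.11. Gbp2 rose by 0.33 ± 0.07. The other probes of Ifit3 (0.63, adjusted p = 0.137) and Gbp2 (0.65, adjusted p = 0.143) were not called. Usp18, a negative regulator of this pathway named after its value was seen, fell by 0.40 ± 0.10 (adjusted p = 0.0303). With median scaling Isg15 and Gbp2 kept their direction and were no longer called (adjusted p = 0.0774 and 0.244). No MHC class I processing gene of 17 was called by limma (0 adjusted over the list alone; median 0.10; camera adjusted p = 0.185).

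Transcription factor genes changed in both directions without a shift of the list. Of 30 measured members 3 rose and 3 fell (5 rose and 4 fell adjusted over the list alone; median 0.02; camera adjusted p = 0.875). Rora rose as given above, Hopx rose by 0.49 ± 0.09 and Ikzf2, which encodes Helios, was at least 1.45-fold higher (adjusted p = 4.8e-06). Irf8 fell by 0.74 ± 0.11. Eomes, a T-box factor of NK cells, and Klf2, both named after their values were seen, fell by 0.60 ± 0.12 and 0.37 ± 0.09.

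Receptors related to DNAM-1 and checkpoint genes also went both ways. Of 7 measured members 1 rose and 1 fell (the same counts adjusted over the list alone; median -0.22; camera adjusted p = 0.842). Tigit, which encodes a receptor that shares ligands with DNAM-1, fell by 0.94 ± 0.14 (adjusted p = 6.8e-04), and Lag3 rose by 0.88 ± 0.14 (adjusted p = 0.00118). Among 18 activating receptors and adaptors Cd160 rose by 0.78 ± 0.09, Zap70 fell by 0.30 ± 0.06 and Syk fell by 0.65 ± 0.16 (2 rose and 4 fell adjusted over the list alone; median -0.08; camera adjusted p = 0.304). The Zap70 call ended with the mean of its probes (-0.21, adjusted p = 0.127) and without samples 5 and 6 of both groups (adjusted p = 0.0627), and its other probes were not called (adjusted p = 0.581 and 0.251). The Syk call ended when any of 6 arrays was left out (adjusted p up to 0.0684). Of 21 chemokine, lipid and adhesion receptors 3 rose and 3 fell (3 and 4 adjusted over the list alone; median -0.08 and mean 0.07, opposite in sign; camera adjusted p = 0.968). The integrin gene Itgax fell by 0.88 ± 0.12 on its representative probe, with an uncalled second probe at -0.30 (adjusted p = 0.349), and Itgae, named after its value was seen, by 0.49 ± 0.07.

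Genes of the cytotoxic list went both ways without a shift of the list by camera. Of 19 cytotoxic effectors Tnfsf10 rose and 2 fell (3 rose and 3 fell adjusted over the list alone), and the median of -0.09 and the mean of 0.01 differed in sign (camera adjusted p = 0.466). Srgn differed by 0.29 ± 0.08 (adjusted p = 0.0534) and was called with the slide as a block (adjusted p = 0.0452). Its other probe was not called (0.31, adjusted p = 0.303). Cst7, a cathepsin inhibitor gene, fell by 0.52 ± 0.12. Prf1, which encodes perforin, fell by 0.28 ± 0.07 (adjusted p = 0.0288), and this call ended when any of 7 arrays was left out (adjusted p up to 0.0703) and with median scaling (adjusted p = 0.0519), and its other probe was not called (-0.37, adjusted p = 0.104).

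Markers of B cells were lower in DNAM-1 positive samples as a list with the preset correlation. None of 12 measured members was called by limma (0 adjusted over the list alone), the median was -0.48, -0.48 on slide 1 and -0.43 on slide 2, and the camera test gave an adjusted p = 0.0206 (adjusted p = 0.521 with an estimated correlation; fry adjusted p = 0.236). At the preset correlation the list passed with the slide as a block (adjusted p = 0.0188), within slide 1 (adjusted p = 7.9e-05) and without samples 5 and 6 of both groups (adjusted p = 9.3e-06). For this list the alternative settings here were all run at the preset correlation, none at the estimated correlation of 0.57. They do not show that the shift holds with it. With the sample number as a replicate block, a pairing the labels do not give, 7 of 12 members were called lower (camera adjusted p = 2.0e-06). Within slide 2 the list did not pass (adjusted p = 0.119), and leaving out any of DNAM-1 negative samples 2, 3 and 5 or DNAM-1 positive sample 6 ended the call (adjusted p = 0.0757, 0.0512, 0.102 and 0.105), as did median scaling (adjusted p = 0.0678). Monocyte and macrophage markers had a median of -0.43, 0.10 on slide 1 and -0.82 on slide 2, with only Ms4a6d of 7 called, at 0.80 ± 0.20 (1 adjusted over the list alone; camera adjusted p = 0.968; any of 7 arrays left out ended the call, adjusted p up to 0.0575). These markers stood highest on the arrays numbered 5 and 6 in DNAM-1 negative cells (1.17 and 1.15 above the 12-array mean) and on array 5 in DNAM-1 positive cells (0.72). Without samples 5 and 6 of both groups, a choice made after seeing the data, 705 features changed (467 higher, 238 lower), 167 by at least 2-fold, and 9 lists shifted.

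**Figure D3:**
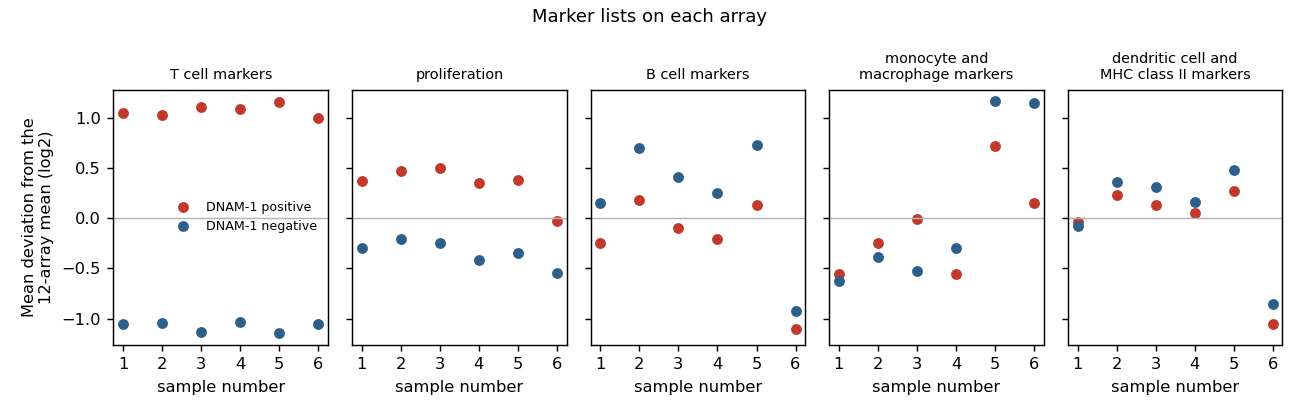
Mean deviation of the members of 5 lists from their mean over the 12 arrays (log2, vertical axis) against sample number (horizontal axis); each point is 1 array. T cell markers separate the groups on every array, whereas the B cell and MHC class II lists are lowest on the arrays numbered 6 in both groups.

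The remaining marker lists of other cell types did not shift by camera. Dendritic cell and MHC class II markers had 1 of 11 members called (1 adjusted over the list alone; median -0.16; camera adjusted p = 0.995), Bst2 at 0.72 ± 0.18, a gene shared with the interferon list whose call ended when any of 7 arrays was left out (adjusted p up to 0.064). Among 4 neutrophil markers Mmp9 rose by 1.01 ± 0.16 (1 adjusted over the list alone; median 0.18; camera adjusted p = 0.221). Among 5 erythroid and platelet markers Car2 rose by 0.99 ± 0.22, with an uncalled second probe at 0.39 (adjusted p = 0.157), and Gp1bb fell by 0.73 ± 0.16, a call that ended without samples 5 and 6 of both groups (adjusted p = 0.0719) (the same counts adjusted over the list alone; median 0.11; camera adjusted p = 0.968). Among 4 ILC2 and ILC3 markers Arg1 was at least 1.47-fold higher (1 adjusted over the list alone; median 0.28; camera adjusted p = 0.085, fry adjusted p = 6.8e-05). Only 1 basophil and mast cell marker was measured, and that list was not tested.

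Few genes of the metabolic and housekeeping lists passed the test. Ribosomal protein genes had a median of 0.05, 0.07 on slide 1 and 0.06 on slide 2, with 3 of 52 members higher and none lower (3 adjusted over the list alone; camera adjusted p = 0.0443, and adjusted p = 0.293 with an estimated correlation), and median scaling turned the sign of the median (-0.01) and ended the call. Rpl13a rose by 0.34 ± 0.07, Rpl21 by 0.35 ± 0.08 and Rpl36a by 0.27 ± 0.07, and the calls of Rpl21 and Rpl36a ended when any of 3 and of 10 arrays were left out (adjusted p up to 0.0546 and 0.084). Median scaling ended all 3 calls (adjusted p = 0.226 for Rpl13a, 0.121 for Rpl21 and 0.22 for Rpl36a), and the other probes of Rpl21 were not called (adjusted p = 0.162 and 0.333). The list also failed within slide 1 (adjusted p = 0.25) and without any of DNAM-1 negative samples 4, 5 and 6 or DNAM-1 positive samples 2 and 3 (adjusted p between 0.061 and 0.116). Of 65 oxidative phosphorylation genes only Cox6a2 changed, falling by 1.55 ± 0.12 (1 adjusted over the list alone; median -0.01; camera adjusted p = 0.806). Of 14 glycolysis genes Pfkm (0.45 ± 0.10) and Slc2a3 (0.23 ± 0.07) rose (3 adjusted over the list alone; camera adjusted p = 0.906), Slc2a3 losing its call with the slide as a block (adjusted p = 0.0552) and without any of 11 arrays (adjusted p up to 0.11). The Pfkm call ended with median scaling (adjusted p = 0.0978) and with the mean of its probes (0.23, adjusted p = 0.144), and its other probes were not called (0.18 and 0.05). Of 18 cholesterol synthesis genes Fdps rose by 0.33 ± 0.08 (1 adjusted over the list alone; camera adjusted p = 0.968; any of 6 arrays left out ended the call, adjusted p up to 0.0669, as did median scaling, adjusted p = 0.364). The median of the cholesterol list, -0.0029, and of the glycolysis list, -0.0018, lay below 0 although camera placed both upwards. Of 22 immediate early and stress genes Ier3 rose by 0.68 ± 0.14 while Dusp2, Zfp36 and Nr4a2 fell by 0.30, 0.37 and 0.50 (2 rose and 6 fell adjusted over the list alone; median -0.10; camera adjusted p = 0.0996, fry adjusted p = 0.00563). The Dusp2 call ended with the mean of its probes (adjusted p = 0.0849), and those of Zfp36 and Nr4a2 without samples 5 and 6 of both groups (adjusted p = 0.0759 and 0.18).

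Outside the lists, Aqp9, a water and glycerol channel gene, was at least 8.61-fold higher in DNAM-1 positive cells (adjusted p = 9.8e-10). The death receptor gene Tnfrsf25 rose by 2.75 ± 0.16, with 5 of 6 DNAM-1 negative arrays above background, and Gramd3 rose by 2.71 ± 0.20. Cyp17a1 fell by 2.49 ± 0.18 on the log2 scale (adjusted p = 6.4e-07), Mcam by 1.64 ± 0.13, the phosphatase gene Ptprk by 1.59 ± 0.10 and Cmya5 by 1.48 ± 0.14. Dpysl5 fell by 1.75 ± 0.13 and was above background on 3 of 6 DNAM-1 positive arrays. Slc37a2, the cadherin gene Cdh22 and Enc1 fell by 1.40 ± 0.08, 1.34 ± 0.25 and 1.22 ± 0.08. Sspn was at least 2.03-fold and the ion exchanger gene Slc24a2 at least 1.64-fold lower in DNAM-1 positive cells.

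The difference between the groups was compared between the slides. All 85 called genes named by the rule had the same sign on both slides. The agreement in sign is no separate evidence, because these genes were called on the arrays of both slides together. Where the groups do not overlap, the sign on each slide is fixed. Of the 85 genes, 83 remained called with the slide as a block, 53 on slide 1 alone, 45 on slide 2 alone and 72 without samples 5 and 6 of both groups. The group by slide interaction of limma called 0 features, with 278 at an unadjusted p under 0.05 where 610.65 would fall by chance (smallest adjusted p = 1.00). All 10 list shifts passed with the slide as a block.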

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

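The tests of explanations in this part were chosen after the results were seen. The values below lay far from the other samples of their group by Dixon's outlier test; 23 of 332 groups of values did so, and chance flags about 1 in 20 groups, or 16.6 here.

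B cell and MHC class II transcripts were low on the arrays numbered 6. The B cell list stood at -0.92 in DNAM-1 negative sample 6 (the others between 0.16 and 0.73, relative to the 12-array mean) and at -1.11 in DNAM-1 positive sample 6 (the others between -0.24 and 0.18), and the dendritic cell and MHC class II list at -1.05 in DNAM-1 positive sample 6. Blk was 4.47 in DNAM-1 negative and 4.40 in DNAM-1 positive sample 6, Fcer2a 5.34 and Cd83 6.26 in DNAM-1 positive sample 6. In DNAM-1 positive sample 6 the proliferation list stood at -0.029, the ribosome biogenesis list at -0.11, Cxcr3 at 11.08 and Cxcr6 at 5.37. In DNAM-1 negative sample 6 Trgv4 was 4.74, Klrb1b 7.82, Il13 6.19 and the DNAM-1 receptor family list -0.43. The Trgv4 and Blk values were background readings. They lay below the lowest signal of a detected probe on their arrays (4.90 in DNAM-1 negative and 4.83 in DNAM-1 positive sample 6).

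These markers, and those of monocytes, differed between sample numbers. By the array labels, both samples of a number lay side by side on the same slide. Any relation between same-numbered samples given below may therefore also reflect slide or position. The slide as the whole reason is argued against, because within slide 2 the monocyte list ranged over 1.27 in DNAM-1 positive and 1.47 in DNAM-1 negative samples. A cell preparation common to both samples of a number may account for the B cell part: the B cell list correlated at r = 0.998 between same-numbered samples over 6 numbers (exact permutation p = 0.00278, adjusted 0.00556; rho = 0.943, exact permutation p = 0.0167, adjusted 0.0333), and at 0.99 without numbers 5 and 6. For monocyte markers, the other of 2 relations computed, r = 0.816 (exact permutation p = 0.0458, adjusted 0.0458; rho = 0.771, exact permutation p = 0.103, adjusted 0.103) fell to -0.12 without numbers 5 and 6, so it rests on those samples. Samples 5 and 6 are argued against as the source of most called genes, since 66.99% of the calls remained without them. For the other calls this stays open, as fewer arrays also end calls. Leaving out these samples does not test differences in B cell markers as a source. The B cell markers Blk and Vpreb3 were then called lower by limma (adjusted p = 0.0122 and 0.0204). No biological explanation was tested.

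DNAM-1 negative sample 3 was high for Ncr1 (9.87), Cma1 (12.78), Cst7 (11.85) and Cd37 (11.14). DNAM-1 negative sample 5 had Sspn at 5.56 and Gbp2 at 10.49. Arg1 was 5.83 in DNAM-1 positive sample 1, and the mature NK list stood at -0.29 in DNAM-1 positive sample 2.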

How the results depend on the processing

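Leaving out samples 5 and 6 of both groups was chosen after the results were seen; the other alternatives were planned. The 827 changed features ranged from 560 to 1026 over the alternatives with at least 4 arrays per group. Each slide alone, with 3 arrays per group, gave 328 and 174 (245 and 129 higher, 83 and 45 lower), from fewer samples. Of the 827, 796 remained called with the slide as a block and 554 without samples 5 and 6 of both groups. Median scaling gave 285 higher features, and the count at least 2-fold fell from 149 to 32 without background correction and to 38 with the deposited values, which lack it, since uncorrected background compresses ratios. Leaving out 1 array gave between 202 and 335 lower features (202 without DNAM-1 positive sample 2). An estimated correlation left 6 of 10 list shifts. Averaging the probes of Jak1 turned its sign (0.0432, adjusted p = 0.882; over its alternatives adjusted p from 0.00644 to 0.882), as its probes conflict. The Cd226 difference lay between 2.46 and 4.88 in every alternative. For the other named genes, apart from leaving out 1 array, 1819 values kept direction and side of the threshold, 120 lost the call, 43 gained one and 1 reversed; the causes were not tested. For lists these were 480, 15, 12 and 0. With 1 array left out, 1447, 77, 12 and 0 for genes and 345, 9, 0 and 0 for lists. Transcripts whose probe was above background on no array of the lower group are given bounds. Differences of others near background there, such as Cd226, Tmem176b and Il2, are given as fitted, and their size is uncertain.

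With the sample number as a replicate block 1026 features changed, 724 of the 827 among them, and 9 lists shifted. The ribosomal protein list no longer passed (camera adjusted p = 0.0522), and 4 of 11 dendritic cell and MHC class II markers were called lower. The B cell list then had 7 of 12 members called lower (camera adjusted p = 2.0e-06 at the preset correlation), and its mean was lower in the DNAM-1 positive sample of all 6 numbers. Deviations of same-numbered samples from their group means correlated between 0.07 and 0.52, over 0.1 in 5 of 6 numbers, and 8 of 12 samples correlated best with their own number. This is a hint from the data and not from the design. Both samples of a number also lay side by side on the same slide, so slide and position cannot be told apart from pairing here.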

Other observations

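The comparison with other splits of the arrays was planned; the tests of T cell explanations were chosen after the results were seen.

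Some transcripts were above background on all arrays of 1 group and on none of the other, 15 genes in DNAM-1 positive and 3 in DNAM-1 negative samples. Besides those already described, and named here after their values were seen, these included Gpr15, a homing receptor gene of T cells, at least 4.09-fold higher (adjusted p = 9.5e-11), and Trbv13-1, a T cell receptor beta chain segment, at least 2.15-fold higher in DNAM-1 positive samples (adjusted p = 1.3e-06). Dgkh, a diacylglycerol kinase gene, was at least 1.83-fold lower (adjusted p = 2.4e-05).

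Chance assignment of arrays is argued against for the number of called genes. Of 100 splits of the 12 arrays into 6 and 6, drawn from 462, only 1, the real one, called as many as 827, and the highest other split called 11. The split by slide called 0. All other splits mix arrays of both groups, so the group difference enters their spread and holds their counts down.

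Cd3d, Cd3e and Cd3g transcripts were higher in DNAM-1 positive samples although the sort removed CD3 positive cells. CD4 or CD8 T cells among the sorted cells stay open. Of the 13 T cell markers only the 9 measured could be called, and 8 were called higher. Trbv13-1 went the same way, while Cd8b1 differed by 0.04 ± 0.12. No probe of Cd4, Cd5, Cd8a, Themis or Cd40lg, genes picked after the results, was above background in DNAM-1 positive samples (0 of 54 probe and array pairs). All but Cd40lg are the list members that the detection filter had left out. The low count was therefore largely fixed by the choice of genes and does not decide the question. A Cd4 probe was above background on 2 DNAM-1 negative arrays, and no T cell sample was used to show how these probes respond. Stray T cells in amounts that vary between sorts stay open too. The SD of Cd3e over the DNAM-1 positive arrays was 0.254 of the median SD of the B cell markers there (0.117 against 0.459, up to 0.415 with 1 array left out). The lowest SD of a B cell marker was that of Cd37, 0.116. Cd37 stood at 10.42 on these arrays, against 5.60 for Blk and 6.05 for Fcer2a. Its spread may therefore not be that of stray B cells, and the comparison with it does not decide the question. Gamma-delta T cells also stay open and could contribute in a constant amount: 2 of 7 of their transcripts were called higher, Trgv4 and Cd163l1 (0.92, adjusted p = 4.5e-04), while Sox13 was above background on 1 DNAM-1 positive array and Il17a, Trgv5 and Trgv6 on none. Trgv7 was not called (0.21, adjusted p = 0.399), nor was Blk, which is also a B cell marker (-0.80, adjusted p = 0.309). T cells could also add to the ILC1, immature NK and cytokine lists, since T cells too transcribe genes such as Il7r, Thy1 and Il2, and this was not tested. Transcription of these genes in NK cells themselves stays open as well and was not tested. The share of ILC1 in each sorted sample was not measured, so which cells account for the ILC1 list stays open too.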
